A study of Mus musculus with 15 samples.

How the data were processed

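Poly(A)-selected RNA from the ventricles of 15 wild-type C57BL/6 mice aged 10 weeks was measured by Illumina RNA sequencing, per the labels' protocols. The labels give 3 groups of 5 biological replicates. The vehicle group received saline. The AngII group carried a subcutaneous pump delivering angiotensin II, a peptide hormone that raises blood pressure, at 1000 ng/kg/min. The AngII plus OA group carried the same pump and received oleic acid (OA), a monounsaturated fatty acid, at 160 mg/kg in 0.3 mL per mouse per day. The groups were taken from the sample titles and the series' design text, and every column of the table matched a title.

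The deposited table gives FPKM (fragments per kilobase of gene, scaled to the size of the library) as the authors computed them, for 36653 gene identifiers in each library. The aligner HISAT2 2.0.4 and the build name mm8 come from the submitters' processing notes. The read counter, gene annotation, strand setting and FPKM program are not given in the sources used here. A protocol sentence on short reads and Bowtie concerns another data type and was not taken to describe these libraries. Gene symbols came from GENCODE M21, which matched 36464 of the identifiers. That annotation was built on another genome build than the one named in the notes, so it served for symbols, lengths and GC content and no coordinates are printed.

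The FPKM of a gene rose in steps between libraries, so whole reads could be recovered. Of the 28996 genes above 0, 99.7% gave whole reads within a tolerance of 0.02, and 86.2% did so with the summed exon length of the reference annotation. For the others the step came from the gene's own values, so whole reads are a weaker check there. The recovered libraries held 22.9 to 26.5 M reads in genes. The FPKM denominators were 24.5 to 28.3 M. Genes with a mean FPKM of 0.5 to 1 rested on a median of 57.1 reads per library, and genes with a mean FPKM of at least 5 on 1193. Because FPKM divides by a total that includes mitochondrially encoded RNA, a change in that share moves the FPKM of every other gene. Reads of close paralogs, such as the actin genes Acta1 and Acta2 or the neighbouring myosin genes Myh6 and Myh7, and of genes that overlap on opposite strands cannot be told apart with certainty, because the handling of shared reads is not given. No pair of replicates agreed within sampling noise (smallest chi-square per degree of freedom 25.3), so each library counted as 1 replicate. Xist stayed at or under 0.0257 FPKM and 4 Y-linked genes were above 0 in 15 of the 15 libraries.

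Changes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, over 13121 genes with a mean FPKM of at least 0.5. All 15 libraries entered 1 fit with group as the only term, so that the groups shared an estimate of the spread. Fold changes are differences on the log2(FPKM + 1) scale and understate the change of genes with low values. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted per comparison. Tests were 2-sided. Gene lists of pathways and cell type markers were tested with limma's camera, which compares the members of a list with all other genes, at a preset correlation of 0.01, adjusted over the 36 lists with a tested member. The T cell list had 0 members tested. Camera with a correlation estimated per list, and an exact permutation test of each list's mean value per library, were alternatives; the smallest p that 5 against 5 libraries can give is 0.00794. Adjusted over 36 lists, 1 list at that p alone reaches 0.286, and at least 6 lists at it, or more at a larger p, are needed to pass, so a list that misses in this test has not been shown to be unchanged. For each list the number of members called was also computed adjusted over the list alone. Such a count is not adjusted for the other lists or genes.

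AngII plus OA against AngII and AngII against vehicle share the AngII libraries with opposite sign, which alone gives a negative slope between their changes. The 5 AngII libraries were therefore divided between the comparisons, 2 to 1 and 3 to the other, in 20 ordered ways, genes were called again in each, and the slope was averaged. A minimum of 10 called genes for a slope was set after the table had been seen. Unchanged groups were simulated for comparison, with independent noise per gene and the same spread in the 3 groups.

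The named genes followed a rule. They were 16 fixed genes, the 8 largest rises and 8 largest falls among called genes with a symbol and a mean FPKM of at least 1 in the higher group (with no gene called, the 5 smallest p), and up to 4 called members of each list described (with none called, the 2 most abundant). The groups, lists, tests, alternatives and this rule were fixed before the data were examined. Some genes that the rule names are not reported here. Which lists are described was decided after their results were seen. Alternatives covered the pseudocount, the filter, 2 normalizations, a replicate block, the libraries in the fit, the trend, robust and weighted fits, a fold limit and leaving out each library. Others were added after the data had been seen: an atrial marker score as a covariate (mean log2 value of Sln, Myl4, Myl7 and Bmp10), leaving out AngII replicate 2 together with that covariate, or in AngII plus OA against vehicle, limma voom on the recovered reads, FPKM rescaled without mitochondrially encoded genes, the exact permutation of list means, and other scalings of the oxidative phosphorylation list set against the cardiomyocyte markers.

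The scripts were tested on simulated data for AngII against vehicle with 13042 genes, of which 200 were changed. They recovered 23.9% of the genes changed 1.5-fold, 59.7% of those changed 2-fold and 92.4% of those changed 4-fold. Of the calls, 10% fell on unchanged genes, and 0 genes were called when none was changed. The simulation drew each gene independently with the same spread in every group, and it held no outlying library. These rates may therefore not hold for the real libraries. A true slope of -0.5 was returned as -0.466 with divided libraries. Library measures were compared with exact permutation tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading the table and for the figures.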

Results

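The 15 heart libraries, 5 each from vehicle, AngII and AngII plus OA mice, held 22.9 to 26.5 M reads in genes. Between 10990 and 11528 genes reached 1 FPKM. Mitochondrially encoded genes took 47.1% ± 2.52 of the FPKM in vehicle hearts, 41.1% ± 5.20 in AngII hearts and 42.4% ± 3.10 in AngII plus OA hearts (SD, n = 5 each). The share was lower in AngII plus OA than in vehicle (exact permutation p = 0.0397). The differences of AngII from vehicle (exact permutation p = 0.0635) and of AngII plus OA from AngII (exact permutation p = 0.651) did not pass. Principal component 1 held 29.0% of the variance and placed AngII replicate 2 at 66.1, far from the other libraries, which lay between -17.2 and 8.98. Transcripts of atrial muscle varied widely within every group. Myl7, an atrial myosin light chain, ranged from 1.05 FPKM in AngII plus OA replicate 2 to 1446 FPKM in AngII replicate 2. That library also held the most of 3 transcripts of other cell types, chosen after their values were seen. The adipocyte gene Cfd was at 252 FPKM there and at most 69.7 in the other libraries, the mesothelial gene Msln at 63.1 and at most 6.06, and the immunoglobulin gene Ighm at 49.8 and at most 9.60. Adipocyte RNA was not limited to that library. Adipoq was at 23.4 FPKM in AngII replicate 2, 10.2 in AngII replicate 4 and at most 2.24 in the other libraries. The mean atrial marker score did not differ by test between AngII and vehicle (exact permutation p = 0.929), AngII plus OA and AngII (exact permutation p = 0.802) or AngII plus OA and vehicle (exact permutation p = 0.762).

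**Figure D1:**
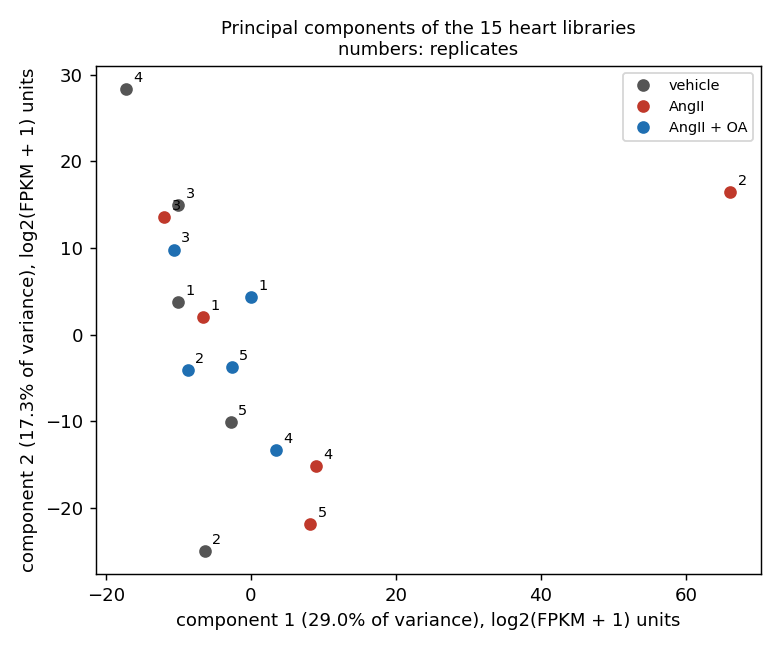
Scores of the 15 libraries on principal components 1 (horizontal) and 2 (vertical) of log2(FPKM + 1), with each point a library coloured by group and numbered by replicate. AngII replicate 2 lies at 66.1 on component 1 (29.0% of the variance), and the other libraries lie between -17.2 and 8.98.

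AngII against vehicle asks which transcripts angiotensin II changed in the ventricle. Called genes included 19 of 34 on the extracellular matrix list and 3 of 16 on the fetal and hypertrophic list, all higher, although both lists had an adjusted p = 0.317 with an estimated correlation. Acta1 (ENSMUSG00000031972), the skeletal alpha-actin of the fetal heart, rose from 107 ± 24.0 to 1005 ± 614 FPKM (SD, n = 5; log2 change 2.96, SE 0.64, adjusted p = 0.0335). Thbs4 (ENSMUSG00000021702), a matricellular thrombospondin, rose from 2.78 ± 1.20 to 49.1 ± 63.8 FPKM (log2 change 3.13, SE 0.58, adjusted p = 0.0165). Cilp (ENSMUSG00000042254), a matrix protein, rose from 4.95 ± 1.31 to 47.1 ± 36.8 FPKM (log2 change 2.78, SE 0.43, adjusted p = 0.0114). Timp1, an inhibitor of metalloproteinases, rose by 2.43 on the log2 scale. The collagen cross-linking enzyme Lox rose by 2.30, the matricellular protein Postn by 2.16 and the microfibril protein Mfap5 by 2.07. In AngII replicate 5, Thbs4 stood at 163 FPKM against 13.9 to 27.7 in the other AngII libraries.

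In all, 197 of 13121 genes were called by limma, 166 higher and 31 lower. The AngII and vehicle values did not overlap for 498 genes, or 3.80% of those tested, where chance gives 0.794%. The largest falls were smaller than the largest rises. The muscle chloride channel Clcn1 fell by 1.14 on the log2 scale. The anoctamin Ano10 (ENSMUSG00000037949) fell by 1.14, from 11.3 ± 1.59 to 4.60 ± 0.853 FPKM, and the potassium channel subunit Kcnv2 fell by 1.01. Ttll1, a tubulin-modifying enzyme, fell by 0.93, BB218582 fell by 0.90, Ky fell by 0.88 and the ciliary transport gene Ift81 fell by 0.87. Banf2os, an opposite-strand transcript whose reads cannot be told from those of its partner without strand information, fell by 0.89.

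The extracellular matrix list was higher with the smallest p of all lists. Of its 34 tested members 19 rose, 29 when adjusted over the list alone, and all 34 were higher. The median log2 change was 1.09 (camera adjusted p = 7.39e-25; adjusted p = 0.317 with an estimated correlation). Col1a1 and Col3a1 encode the main fibrillar collagens of the heart. Col1a1 rose from 10.7 ± 0.698 to 35.2 ± 15.8 FPKM (log2 change 1.52, SE 0.30, adjusted p = 0.0250), and Col3a1 from 25.7 ± 6.59 to 86.5 ± 45.5 FPKM (log2 change 1.62, SE 0.30, adjusted p = 0.0165). Among TGF-beta and myofibroblast genes, 5 of 20 rose, 9 adjusted over the list alone, with a median of 0.54 (adjusted p = 2.76e-05; adjusted p = 0.317 with an estimated correlation). Besides Thbs4 and Postn these included Ltbp2, a latent TGF-beta binding protein (log2 change 1.86), and the secreted protein Cthrc1 (1.60). Of the fetal and hypertrophic genes, 3 of 16 rose, 9 adjusted over the list alone, with a median of 0.85 (adjusted p = 2.76e-05; adjusted p = 0.317 with an estimated correlation). They were Acta1, the stress-responsive titin-binding protein Ankrd1 (from 354 ± 97.1 to 1098 ± 215 FPKM, log2 change 1.66) and the intermediate filament desmin, Des (0.68).

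Several fixed markers did not pass. Nppa, which encodes atrial natriuretic peptide, averaged 172 ± 232 FPKM in AngII and 37.3 ± 30.1 in vehicle (log2 change 1.82, SE 0.66, adjusted p = 0.178). Its highest value, 585 FPKM, was in AngII replicate 2, the library with the most atrial transcripts. The next highest, 97.3 FPKM, was in AngII replicate 5, where the atrial gene Myl7 was at 1.49 FPKM. The related peptide Nppb had a log2 change of 0.95 (adjusted p = 0.256), the myosin heavy chain Myh7 -0.35 (0.446) and Myh6 -0.16 (0.623). The smooth muscle actin Acta2 had 0.01 (0.990) and Ccn2, a connective tissue growth factor, 1.46 (0.117). Genes of fatty acid use did not pass either. Pdk4, an inhibitor of pyruvate oxidation, had a log2 change of 1.29 (adjusted p = 0.271), Angptl4 1.54 (0.155), Cpt1b 0.11 (0.849) and Ucp3 0.23 (0.875).

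Macrophage markers were higher. Of 14 members 4 rose, 9 adjusted over the list alone, with a median log2 change of 0.57 (adjusted p = 1.23e-06; adjusted p = 0.317 with an estimated correlation). The complement genes C1qb (from 55.2 ± 5.33 to 104 ± 19.7 FPKM, log2 change 0.88), C1qa (0.79) and C1qc (0.70) and the scavenger receptor Cd163 (0.90) rose. With 1 library left out, C1qb kept its call in every fit, while C1qa, C1qc and Cd163 lost theirs in several. Without AngII replicate 5 their limma adjusted p was 0.0855, 0.0928 and 0.0950. Without AngII replicate 2 that of Cd163 was 0.0681. Autophagy and lysosome genes had a median of 0.38 (adjusted p = 0.00131; adjusted p = 0.317 with an estimated correlation). The 2 of 16 that rose, 6 adjusted over the list alone, were the cathepsins Ctss (1.30) and Ctsk (1.28), which macrophages also make. NADPH oxidase subunits had a median of 0.39 (adjusted p = 0.00144; adjusted p = 0.346 with an estimated correlation), with Ncf4 the 1 of 7 that rose (0.67) and 5 adjusted over the list alone. Over genes with a mean FPKM of at least 5 it kept 1 member and had no test. Antioxidant genes had a median of 0.25 (adjusted p = 0.00429; adjusted p = 0.368 with an estimated correlation). The uncoupling protein Ucp2 (0.85) and extracellular superoxide dismutase Sod3 (0.75) were the 2 of 19 that rose, 6 adjusted over the list alone. The list's call was lost without AngII replicate 2 (0.0768), at a median of 0.16. The antioxidant median was 0.11 after quantile normalization, 0.17 after shifting each library to 1 median and 0.11 with FPKM rescaled without mitochondrially encoded genes. The autophagy median was 0.24 after quantile normalization and 0.23 with FPKM rescaled. Cytokines, chemokines and adhesion molecules did not pass as a list (median 0.28, adjusted p = 0.187), although the chemokines Ccl5 (1.35) and Ccl9 (1.15) were the 2 of 24 that rose, 5 adjusted over the list alone. It passed without AngII replicate 3 (0.0475) or vehicle replicate 3 (0.0282).

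Cell cycle genes had a median log2 change of 0.32 (adjusted p = 0.00103; adjusted p = 0.507 with an estimated correlation). The spindle gene Nusap1 was the 1 of 21 that rose (0.49), while adjusted over the list alone 9 rose and 1 fell. Over genes with a mean FPKM of at least 5 the cell cycle list kept 1 member and had no test. Endothelial markers had a median of 0.32 (adjusted p = 0.0259; adjusted p = 0.462 with an estimated correlation), with 0 of 12 called by limma and 2 rising adjusted over the list alone. Fabp4 was at 459 ± 116 against 324 ± 79.9 FPKM and Cdh5 at 72.7 ± 13.2 against 61.0 ± 4.27. The endothelial call was lost without AngII replicate 4 (0.0999), vehicle replicate 3 (0.0729) or vehicle replicate 4 (0.109), with a median of 0.18 without AngII replicate 4, and over genes with a mean FPKM of at least 5 (0.0952). The endothelial median was 0.17 after quantile normalization and 0.18 with FPKM rescaled without mitochondrially encoded genes. Fibroblast markers did not pass as a list (median 0.35, adjusted p = 0.0619), but passed without AngII replicate 5 (0.0406), vehicle replicate 4 (0.0495) or vehicle replicate 5 (0.0211). Pi16 rose from 22.5 ± 3.52 to 61.7 ± 17.6 FPKM (log2 change 1.39), the 1 of 9 that rose, 5 adjusted over the list alone. Atrial markers had a median of -0.05 (adjusted p = 0.583) and a mean of 0.09, with 0 of 5 called, also adjusted over the list alone. Myl7 averaged 400.0 ± 607 against 223 ± 196 FPKM and Sln 159 ± 283 against 68.7 ± 65.2. Without AngII replicate 2 the atrial list had a median of -0.86 and passed (0.0194).

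Genes of mitochondrial energy use were lower as lists, with 0 members called in each, also adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.11, with 25 of 28 members lower (adjusted p = 4.02e-05; adjusted p = 0.462 with an estimated correlation). Fatty acid beta-oxidation genes had -0.21, with 18 of 21 lower (adjusted p = 6.03e-05; adjusted p = 0.495 with an estimated correlation), and citric acid cycle genes -0.23, with 12 of 12 lower (adjusted p = 6.03e-05; adjusted p = 0.462 with an estimated correlation). By exact permutation of list means these lists did not pass, with unadjusted p = 0.389, 0.413 and 0.278 in that order. Cox7b was at 771 ± 38.7 against 829 ± 99.95 FPKM, Atp5a1 at 745 ± 236 against 887 ± 175, Ech1 at 423 ± 63.1 against 584 ± 46.1 and Idh2 at 538 ± 106 against 661 ± 84.0. Acadl, at 422 ± 47.0 against 417 ± 59.2, differed little. Without AngII replicate 2 these lists passed with medians of -0.02, -0.09 and -0.09. The first of them, oxidative phosphorylation, had -0.20 without AngII replicate 1, -0.20 without AngII replicate 3, -0.07 without AngII replicate 5 and -0.18 without vehicle replicate 4. Beta-oxidation had -0.34, -0.32, -0.12 and -0.09 without those same libraries. Under other scalings the medians were farther from 0. Oxidative phosphorylation had -0.26 after quantile normalization, -0.20 after shifting each library to 1 median and -0.26 with FPKM rescaled without mitochondrially encoded genes. Beta-oxidation had -0.36 and the citric acid cycle had -0.37 after quantile normalization, and they had -0.36 and -0.38 with FPKM rescaled.

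Calcium handling and ion channel genes had a median of -0.19 (adjusted p = 2.76e-05; adjusted p = 0.338 with an estimated correlation), with Kcnv2 the 1 of 20 that fell, also adjusted over the list alone. Exact permutation of the list mean gave an unadjusted p = 0.238. The median was -0.08 without AngII replicate 2, -0.32 without AngII replicate 3, -0.30 after quantile normalization and -0.32 with FPKM rescaled. Immediate early genes, which respond within minutes to stimuli, had a median of -0.42 with 0 of 15 called, also adjusted over the list alone (adjusted p = 3.07e-05; adjusted p = 0.368 with an estimated correlation). Exact permutation of their mean gave an unadjusted p = 0.175. Dusp1 was at 34.98 ± 9.53 against 52.3 ± 7.57 FPKM and Ier2 at 29.0 ± 14.8 against 35.6 ± 11.7. Their median was -0.23, -0.65 and -0.26 without AngII replicates 3, 4 and 5. Cardiomyocyte markers had a median of -0.12 with 0 of 13 called, also adjusted over the list alone (adjusted p = 0.0243; adjusted p = 0.578 with an estimated correlation). Exact permutation of their mean gave an unadjusted p = 0.794. Mb, the oxygen store myoglobin, was at 9210.1 ± 1763 against 9888 ± 776 FPKM and Myl2, a ventricular myosin light chain, at 4979 ± 1406 against 6166 ± 1049.6. The cardiomyocyte call was lost without AngII replicate 2 (0.442), vehicle replicate 1 (0.181) or vehicle replicate 2 (0.0676), with a median of 0.04 without AngII replicate 2 and -0.05 without vehicle replicate 1, and after quantile normalization (0.516). Its median was -0.20 after shifting each library to 1 median and -0.27 with FPKM rescaled. Fatty acid uptake, storage and PPAR target genes did not pass (adjusted p = 0.660, 0 of 23 called, also adjusted over the list alone). The sign of their median, 0.06, turned negative under every other scaling tried. Fabp3 was at 3013 ± 669.9 against 2839 ± 348 FPKM and Lpl at 466 ± 16.8 against 448 ± 37.7.

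Camera passed 20 of the 36 lists, 12 higher and 8 lower. With an estimated correlation 0 passed, and 5 had an unadjusted p under 0.05. By exact permutation of list means 11 had an unadjusted p under 0.05, and 5 of these had the smallest p possible, 0.00794. After adjustment, where at least 6 lists at that p or more at a larger one are needed, 0 passed. The split of called genes moved with the scaling. It was 69 higher and 40 lower after quantile normalization, 103 and 57 after shifting each library to 1 median, and 54 and 50 with FPKM rescaled without mitochondrially encoded genes, which moved the median change of all genes by -0.109. The count was 70 with only the 10 libraries compared. Leaving out 1 library gave 86 without AngII replicate 1, 425 without AngII replicate 3, 70 without AngII replicate 4 and 49 without AngII replicate 5. It gave 79, 128, 70 and 50 without vehicle replicates 2, 3, 4 and 5. Of the 197 genes, 40 passed in all 10 of these fits. Of the 37 named genes among them, 14 did so, among them Col3a1, Postn, Cilp, Mfap5, Ankrd1, Ltbp2, Ccl5, Sod3, Pi16, C1qb, Clcn1, Ano10 and BB218582. Thbs4 lost its call without vehicle replicate 4 (0.05002) or vehicle replicate 5 (0.0521). Acta1 lost it without AngII replicate 1 (0.0826), AngII replicate 4 (0.0866), AngII replicate 5 (0.0735), vehicle replicate 1 (0.0511), vehicle replicate 2 (0.0661), vehicle replicate 3 (0.0550), vehicle replicate 4 (0.0785) or vehicle replicate 5 (0.0917). Col1a1 lost it without AngII replicate 1 (0.0611), AngII replicate 4 (0.0576), AngII replicate 5 (0.0678), vehicle replicate 2 (0.0572), vehicle replicate 4 (0.0583) or vehicle replicate 5 (0.0616). The other named genes lost it in at least 1 of these fits, with an adjusted p of up to 0.123. The named gene that kept its call least often did so in 2 of the 10 fits. Lox, Kcnv2, Nusap1, Ucp2, C1qa, C1qc and Cd163 each lost it without AngII replicate 1, AngII replicate 4 or AngII replicate 5, among others. Leaving out AngII replicate 3 ended 0 of the named calls. None of the 37 changed sign.

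**Figure D2:**
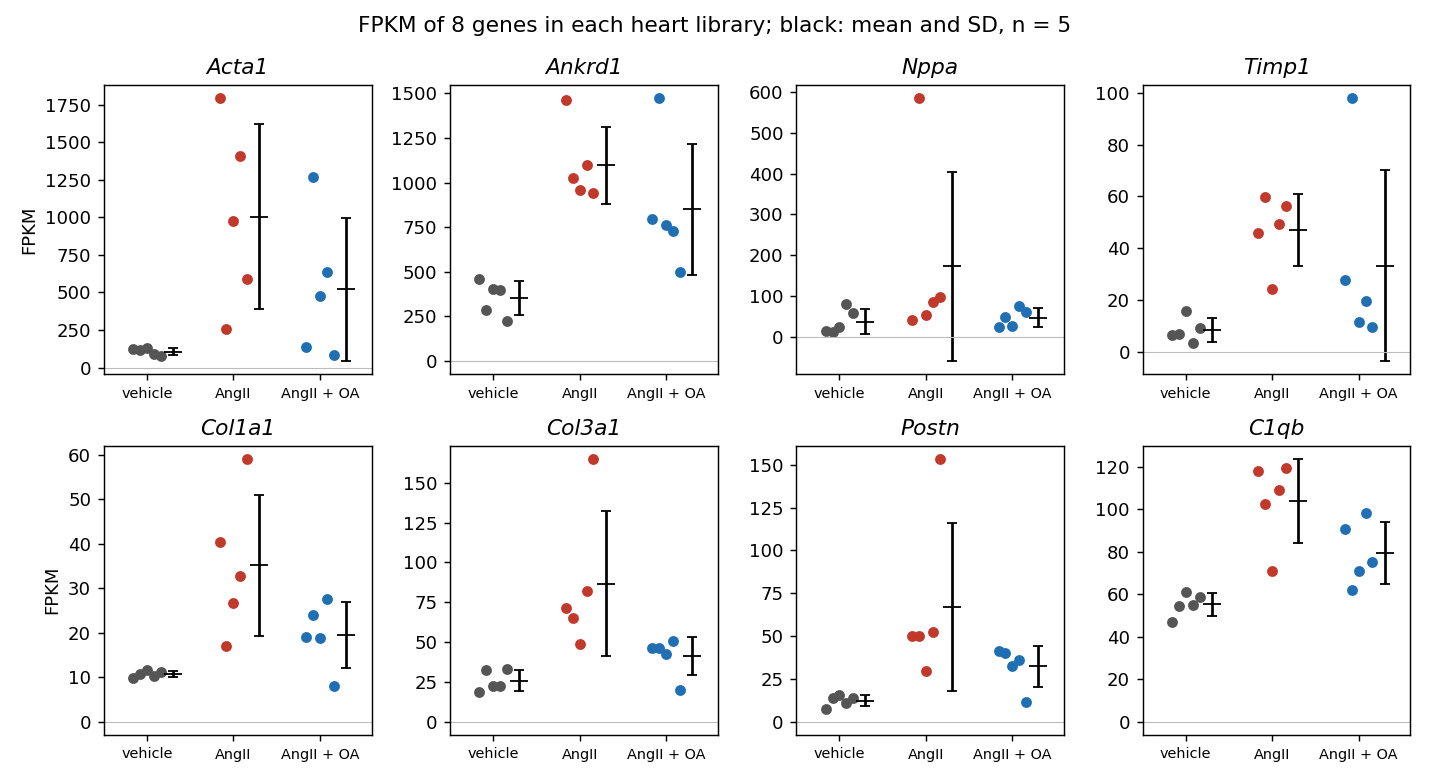
FPKM (vertical axis, linear) of 8 genes in each library of the vehicle, AngII and AngII plus OA groups, with black lines for the mean and SD of 5 libraries. Acta1 averaged 1005 FPKM in AngII and 521 in AngII plus OA hearts against 107 in vehicle, with wide overlap between the AngII and AngII plus OA libraries.

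AngII plus OA against AngII asks what differed with daily oleic acid in hearts under angiotensin II. The labels name no AngII group dosed without oleic acid, so oleic acid cannot be told apart from its daily dosing. By limma, 0 of 13121 genes passed, and the smallest adjusted p was 0.574. At an unadjusted p under 0.05 there were 866 genes, 689 of them lower, and limma voom on the recovered reads also called 0. Extracellular matrix genes were lower as a list, with all 34 tested members lower and a median log2 change of -0.70 (camera adjusted p = 3.24e-17; adjusted p = 0.358 with an estimated correlation; exact permutation p = 0.0159, adjusted 0.286). Adjusted over the list alone, and so not for the other lists or genes, 21 fell. Col1a1 averaged 19.5 ± 7.38 against 35.2 ± 15.8 FPKM in AngII (SD, n = 5; log2 change -0.81, SE 0.30, adjusted p = 0.710). Col3a1 averaged 41.2 ± 12.1 against 86.5 ± 45.5 (-0.99, SE 0.30, adjusted p = 0.706) and Postn 32.3 ± 12.2 against 67.1 ± 49.1 (-0.92, SE 0.39, adjusted p = 0.737). The most abundant members were Dcn (554 ± 168 against 659.6 ± 207) and Sparc (171 ± 36.3 against 305 ± 88.9). Col3a1 and Postn in AngII plus OA replicate 5, at 20.2 and 11.5 FPKM, lay far under the other libraries of the group.

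Cell cycle genes were lower as well, with a median of -0.36, 0 of 21 called by limma and 12 falling adjusted over the list alone (adjusted p = 1.55e-08; adjusted p = 0.358 with an estimated correlation). The 5 smallest p-values of the comparison, none of which passed (adjusted p = 0.574 each), belonged to Trim59 (log2 change -0.54), the collagen-like secreted protein C1qtnf6 (-0.87), the mitotic genes Cdc20 (-0.76) and Cdkn3 (-0.73), and Rasd1 (-1.19). The replication genes Pcna (18.1 ± 0.838 against 18.4 ± 1.87 FPKM) and Mcm6 (3.07 ± 0.529 against 3.07 ± 0.0966) were close in both groups. Endothelial markers had a median of -0.30, with 3 of 12 falling adjusted over the list alone (adjusted p = 0.000648; adjusted p = 0.358 with an estimated correlation). Fabp4 was at 385 ± 74.6 against 459 ± 116 FPKM and Cdh5 at 58.8 ± 8.61 against 72.7 ± 13.2. TGF-beta and myofibroblast genes had a median of -0.32 (adjusted p = 0.00237; adjusted p = 0.418 with an estimated correlation), macrophage markers -0.19 (adjusted p = 0.0246; adjusted p = 0.536 with an estimated correlation) and autophagy and lysosome genes -0.19 (adjusted p = 0.0455; adjusted p = 0.536 with an estimated correlation). These 3 lists had 0 members called, also adjusted over the list alone. Ccn2 was at 83.1 ± 20.9 against 148 ± 132 FPKM, Acta2 at 61.7 ± 17.1 against 62.2 ± 17.8, Lyz2 at 247 ± 64.6 against 268 ± 56.5 and C1qa at 103 ± 16.2 against 129 ± 28.1. Map1lc3a was at 306 ± 47.8 against 261 ± 16.9 and Ctsd at 190.2 ± 25.6 against 211 ± 23.4. The TGF-beta call was lost over genes with a mean FPKM of at least 5 (0.0719), where the cell cycle list kept 1 member and had no test. The macrophage call was lost without AngII plus OA replicate 2 (0.194), AngII replicate 1 (0.0753), AngII replicate 4 (0.0681) or AngII replicate 5 (0.216), with a median of -0.12 without AngII replicate 5. The autophagy call was lost without AngII plus OA replicate 2 (0.203), AngII plus OA replicate 4 (0.0934), AngII replicate 1 (0.0863) or AngII replicate 2 (0.364), with a median of -0.11 without AngII replicate 2. It was also lost after quantile normalization (0.0720, median -0.13), with the atrial covariate (0.0664) and with FPKM rescaled (0.0896).

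Lists of mitochondrial energy use and of muscle were higher, with 0 members called in each, also adjusted over the list alone. Oxidative phosphorylation had a median of 0.25 with 28 of 28 members higher (adjusted p = 1.81e-11; adjusted p = 0.358 with an estimated correlation). Fatty acid beta-oxidation had 0.23 (adjusted p = 1.26e-07; adjusted p = 0.382 with an estimated correlation), and the citric acid cycle 0.22 (adjusted p = 2.85e-07; adjusted p = 0.373 with an estimated correlation). By exact permutation of list means these lists did not pass, with unadjusted p = 0.183, 0.294 and 0.222 in that order. Cardiomyocyte markers had 0.23 (adjusted p = 2.16e-06; adjusted p = 0.358 with an estimated correlation), a call lost after quantile normalization (0.0567, median 0.11). Calcium handling and ion channel genes had 0.15 (adjusted p = 5.30e-05; adjusted p = 0.373 with an estimated correlation). Cox7b was at 925 ± 61.8 against 771 ± 38.7 FPKM, Atp5a1 at 875 ± 116 against 745 ± 236, Ech1 at 594 ± 99.1 against 423 ± 63.1 and Acadl at 475 ± 29.9 against 422 ± 47.0. Idh2 was at 671 ± 34.99 against 538 ± 106, Mb at 10346 ± 333 against 9210.1 ± 1763 and Myl2 at 6675 ± 704 against 4979 ± 1406. The calcium regulators Pln and Atp2a2 were at 1608 ± 227 against 1236 ± 489.5 and 785 ± 137 against 727 ± 263. Myl2 and Mb were lowest in AngII replicate 2, at 2555 and 6173 FPKM. Without AngII replicate 2 the 5 lists still passed, with medians of 0.10, 0.08, 0.10, 0.06 and 0.06 in the order given. Without AngII replicate 3 the calcium list had 0.29, and without AngII replicate 5 beta-oxidation had 0.15.

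The fetal and hypertrophic list did not differ by test between AngII plus OA and AngII (median 0.04, mean -0.08, adjusted p = 0.267), but passed without AngII replicate 4 (0.0442). Acta1 averaged 521 ± 476 against 1005 ± 614 FPKM (log2 change -1.27, SE 0.64, adjusted p = 0.737) and Nppb 937 ± 206 against 1073 ± 849. Cryab, a small heat shock protein, averaged 1460.4 ± 422 against 1315 ± 312, Nppa 47.1 ± 22.5 against 172 ± 232 and Timp1 33.3 ± 36.8 against 47.2 ± 13.9. Myh7 had a log2 change of 0.58 (adjusted p = 0.710) and Myh6 0.31 (0.737). The lipid-responsive genes did not pass. Pdk4 had a log2 change of -1.03 (0.747), Angptl4 -1.11 (0.737), Cpt1b -0.09 (0.945) and Ucp3 -0.52 (0.857). The lists of fatty acid uptake, storage and PPAR targets (adjusted p = 0.853), cytokines, chemokines and adhesion molecules (0.267), immediate early genes (0.669) and fibroblast markers (0.303) did not pass. NADPH oxidase subunits (0.0514) passed without AngII plus OA replicate 1 (0.0341), AngII plus OA replicate 4 (0.0357), AngII plus OA replicate 5 (0.0254), AngII replicate 2 (0.0246) or AngII replicate 3 (0.00586). Antioxidant genes (0.126) passed without AngII plus OA replicate 5 (0.0336) or AngII replicate 5 (0.0160). Atrial markers (0.945, median -0.44) passed without AngII replicate 2 (0.0149), with a median of 0.54. All these lists had 0 members called, also adjusted over the list alone.

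Camera passed 14 lists, 6 higher and 8 lower. With an estimated correlation 0 passed, and 4 had an unadjusted p under 0.05. By exact permutation of list means 5 had an unadjusted p under 0.05, 0 of them at the smallest p possible, and 0 passed after adjustment, with the same limit. Leaving out AngII replicate 3 gave 1 called gene, Rasd1 (log2 change -1.46, SE 0.19, adjusted p = 0.0177).

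**Figure D3:**
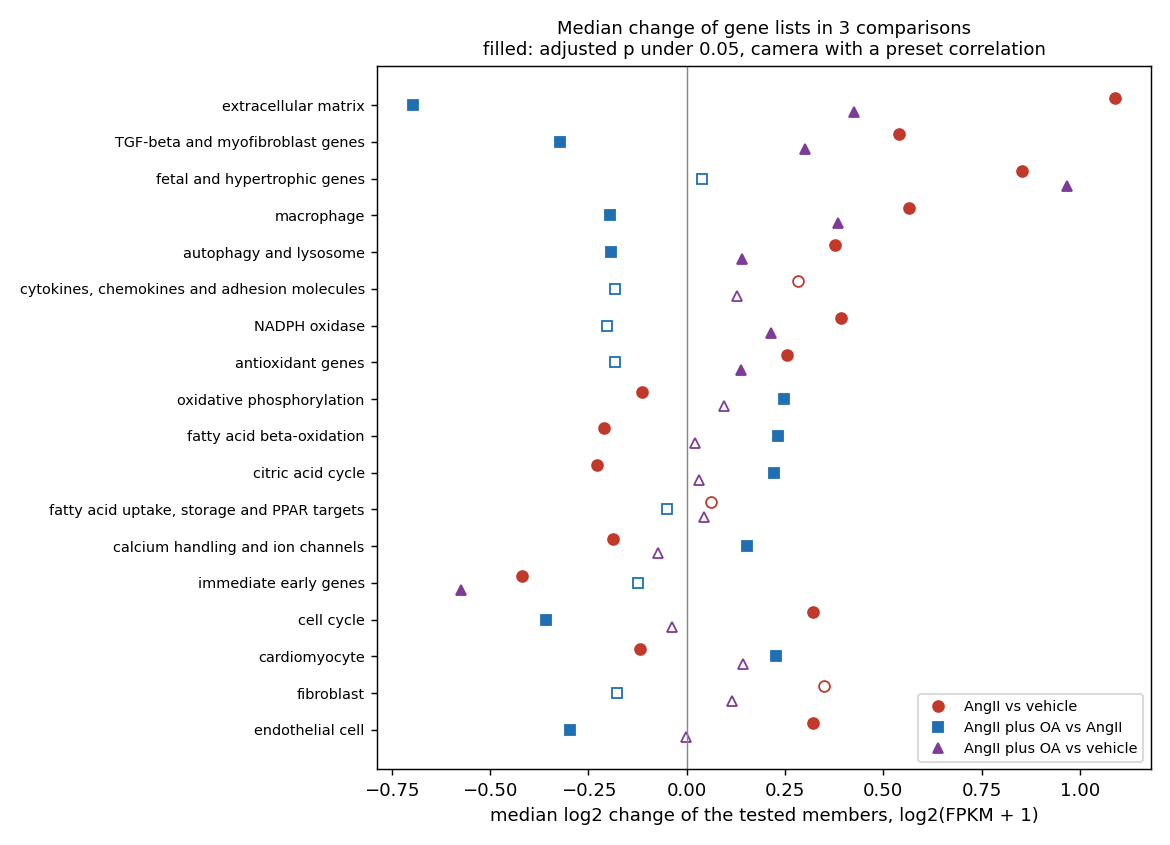
Median log2 change, on the log2(FPKM + 1) scale, of the tested members of 18 gene lists in AngII against vehicle (circles), AngII plus OA against AngII (squares) and AngII plus OA against vehicle (triangles), filled where camera with a preset correlation passed. Extracellular matrix genes lie at 1.09, -0.70 and 0.42, and fetal and hypertrophic genes at 0.85, 0.04 and 0.97.

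All 166 genes higher and all 31 genes lower in AngII than in vehicle had a change of the opposite sign between AngII plus OA and AngII, but the comparisons share the AngII libraries in which those genes were chosen. With the AngII libraries divided between the comparisons, the change with OA had a mean slope of -0.261 on the change with AngII across the called genes (SD 0.135, range -0.491 to -0.00245). This is over the 11 of 20 divisions that called enough genes. The mean correlation across the called genes, which are not independent replicates, was -0.513, and 83.2% of the called genes had the opposite sign. Of 100 groupings of the AngII and AngII plus OA libraries, the real one included, 89 gave a slope and 8 a slope as negative. Chance therefore stays open for this slope. Undivided libraries gave a slope of -0.450. Over all tested genes the undivided slope was -0.564 (r = -0.779, covariance -0.0448), against -0.498 (r = -0.498, covariance -0.0192) in simulated unchanged groups. The difference in covariance was -0.0256. The simulation gave the 3 groups the same spread and independent genes, so a larger spread among AngII libraries could also give such a difference. With divided libraries, the slope over all tested genes was -0.183 (range -0.380 to 0.0275, mean r = -0.212), and 57.9% of them had the opposite sign. Without AngII replicate 5 the slope over called genes was -0.0855, without AngII replicate 1 -0.135, without AngII replicate 4 -0.156 and without AngII plus OA replicate 5 -0.159.

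AngII plus OA against vehicle asks what differed from untreated hearts under both treatments. By limma 0 genes passed, with a smallest adjusted p of 0.926. At an unadjusted p under 0.05 there were 441 genes, and limma voom also called 0. Fetal and hypertrophic genes were higher as a list, with a median log2 change of 0.97, 15 of 16 members higher and 12 rising adjusted over the list alone (camera adjusted p = 1.34e-17; adjusted p = 0.0546 with an estimated correlation; exact permutation p = 0.00794, adjusted 0.214). The smallest p-values, none of which passed (adjusted p = 0.926 each), belonged to Ankrd1 (852 ± 367 against 354 ± 97.1 FPKM, SD, n = 5; log2 change 1.22), the actin regulator Enah (0.90), Rasl11b (1.16), Cystm1 (0.52) and Des (0.63). Acta1 had a log2 change of 1.69 (SE 0.64, adjusted p = 1), Nppb 1.04, Cryab 0.49, Nppa 0.58, Myh7 0.23 and Myh6 0.14.

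Extracellular matrix genes were higher, with 34 of 34 members higher, a median of 0.42 and 1 rising adjusted over the list alone (adjusted p = 4.25e-16; adjusted p = 0.276 with an estimated correlation). Col1a1 had a log2 change of 0.71, Col3a1 0.63, Postn 1.24, Timp1 1.49, Dcn 0.29 and Sparc 0.36. Macrophage markers had a median of 0.39, with 3 rising adjusted over the list alone (adjusted p = 2.69e-08; adjusted p = 0.276 with an estimated correlation), Lyz2 at 0.43 and C1qa at 0.49. TGF-beta and myofibroblast genes had a median of 0.30 (adjusted p = 0.000432; adjusted p = 0.420 with an estimated correlation), with Ccn2 at 0.99 and Acta2 at 0.01. NADPH oxidase subunits had 0.21 (adjusted p = 0.00805; adjusted p = 0.474 with an estimated correlation), with Cyba at 0.12 and Ncf1 at 0.40. Antioxidant genes had 0.14 (adjusted p = 0.00805; adjusted p = 0.474 with an estimated correlation), with Sod1 at 0.12 and the metallothionein Mt1 at 0.78. Autophagy and lysosome genes had 0.14 (adjusted p = 0.00805; adjusted p = 0.425 with an estimated correlation), with Map1lc3a at 0.22 and Ctsd at 0.11. Immediate early genes were lower, with a median of -0.57 (adjusted p = 3.69e-09; adjusted p = 0.276 with an estimated correlation), Dusp1 at -0.61 and Ier2 at -0.57. In these last 5 lists 0 members were called, also adjusted over the list alone. The NADPH oxidase list kept 1 member and had no test over genes with a mean FPKM of at least 5. Its call was lost without vehicle replicate 1 (0.0745), and its median was 0.14 without AngII plus OA replicate 1 and 0.14 with FPKM rescaled without mitochondrially encoded genes. The antioxidant call was lost without AngII plus OA replicate 5 (0.0630), vehicle replicate 2 (0.0772) or vehicle replicate 5 (0.0506). Quantile normalization ended the antioxidant (0.104) and autophagy (0.0673) calls, at medians of 0.07 and 0.07. With FPKM rescaled the antioxidant and autophagy medians were 0.02 and 0.02.

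Oxidative phosphorylation (median 0.10, adjusted p = 0.176) did not pass, but did without AngII plus OA replicate 2 (0.0468) or AngII plus OA replicate 4 (0.0451). Fatty acid beta-oxidation (0.02, 0.930) and the citric acid cycle (0.03, 0.980) did not pass. The medians of these 3 lists turned negative after quantile normalization and with FPKM rescaled without mitochondrially encoded genes, and that of beta-oxidation also after shifting each library to 1 median. Cardiomyocyte markers (0.14, 0.0654) passed without AngII plus OA replicate 1 (0.0361), AngII plus OA replicate 3 (0.0329), AngII plus OA replicate 4 (0.0382), vehicle replicate 1 (0.00642) or vehicle replicate 2 (0.0439). Fibroblast markers (0.11, 0.0517; 1 rose adjusted over the list alone) passed without AngII plus OA replicate 2 (0.000729), AngII plus OA replicate 5 (0.0300), vehicle replicate 3 (0.0409), vehicle replicate 4 (0.0390) or vehicle replicate 5 (0.0130), and their median turned negative with FPKM rescaled. Cell cycle genes (-0.04, 0.0763) passed without AngII plus OA replicate 2 (0.0225), AngII plus OA replicate 3 (0.0121), vehicle replicate 3 (0.0351), vehicle replicate 4 (0.00994) or vehicle replicate 5 (0.0182). Calcium handling genes (-0.07, 0.0763) passed without AngII plus OA replicate 3 (0.0321), AngII plus OA replicate 5 (0.0213), vehicle replicate 2 (0.0464) or vehicle replicate 5 (0.0259). Cytokines (0.367) passed without vehicle replicate 3 (0.0301). Fatty acid uptake, storage and PPAR targets (adjusted p = 0.698), endothelial (0.563) and atrial markers (0.529) did not pass. Pdk4 had a log2 change of 0.26, Angptl4 0.44, Cpt1b 0.02 and Ucp3 -0.28, with an adjusted p of 1 each.

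Camera passed 11 lists, 9 higher and 2 lower. With an estimated correlation 0 passed, and 5 had an unadjusted p under 0.05. By exact permutation of list means 5 had an unadjusted p under 0.05, 1 of them at the smallest p possible, and 0 passed after adjustment, with the same limit.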

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

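The tests of read number, cardiomyocyte share and fibroblast share were chosen after the result was seen, as were the range given for the atrial test, the exact permutation of list means and the quantile normalization of the cardiomyocyte test; the rescaling without mitochondrially encoded genes was added after the data were seen, and its test, set before its own result, was left out for a time once that result was known and then restored.

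Among 327 groups of 5 values (106 named genes and 3 library measures), 19 held a library far from the other 4, close to the share of about 1 in 20 that chance gives. Of these, 5 were in AngII replicate 2: Cd163 was high at 11.7 FPKM, and Kcnv2 (0.437), Mb (6173), Myh6 (1771) and Myl2 (2555) were low. In other AngII libraries, Corin was low in replicate 4 (13.7) and Thbs4 high in replicate 5 (163). In AngII plus OA hearts, Iigp1 was high in replicate 1 (50.9), Des was high (918) and Lyz2 low (137) in replicate 2, Myh6 was low in replicate 3 (2929), Acadl was low (424) and Ncf4 high (2.85) in replicate 4, and Col3a1 (20.2) and Postn (11.5) were low in replicate 5. In vehicle hearts, Myl7 was low in replicate 1 (1.56), Nusap1 high in replicate 2 (1.06), and Ech1 (505) and Idh2 (520.1) low in replicate 5.

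AngII replicate 2 stood apart from the other libraries, and a low read number is argued against, since 3 libraries had fewer reads in genes. Atrial tissue may be the source, and Myl7 reached 1446 FPKM there, but across genes outside the atrial list the library's deviation correlated at only 0.149 with the atrial trend within groups. That value lay under the bound of 0.2 set in advance against this explanation; the range with 1 library left out, 0.0984 to 0.204, reached past the bound, so the explanation stays open. Adipocyte (Cfd, 252 FPKM), mesothelial (Msln, 63.1 FPKM) and B cell (Ighm, 49.8 FPKM) genes were also highest there, so RNA of other tissue than atrium is open and was not tested. The adipocyte gene Adipoq was at 23.4 FPKM there and also at 10.2 in AngII replicate 4. A stronger response to AngII also stays open, with a mean correlation of 0.0432 over the 6 divisions of the other AngII libraries (range -0.0929 to 0.217), although Acta1 (259.8 FPKM) and Col1a1 (17.1 FPKM) were the lowest of the 5 AngII libraries.

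Oxidative phosphorylation genes were higher with AngII plus OA than with AngII, at a median of 0.25, but the call was lost with an estimated correlation (adjusted p = 0.358), and exact permutation of list means gave p = 0.183. The share of mitochondrially encoded RNA is argued against, since rescaling without it left 0.277, and so are gene length and GC content, since 1288 matched genes had a median of -0.0392. A larger share of cardiomyocyte RNA stays open: the list minus the cardiomyocyte markers differed by -0.0187 between the groups as deposited (exact permutation p = 0.825), but by 0.108 after quantile normalization (exact permutation p = 0.143), where the medians of the list, 0.245, and of the markers, 0.107, lay farther apart than the bound of 1.5 times allows, and neither p shows equality. AngII replicate 2 carries much of the difference. Without it the median was 0.103, under the bound set in advance, which alone met the criterion for that library as the cause. The list still passed its camera test without that library, so a smaller change in the other libraries is not excluded. An effect of oleic acid, or of its daily dosing, stays open and untested apart from these.

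Extracellular matrix genes were lower with AngII plus OA than with AngII, at a median of -0.70. AngII replicate 5, which had the highest Col1a1 and Postn, is argued against as the sole cause, since the median without it was -0.563 and the list passed. Leaving out each library in turn gave medians of -0.804 to -0.522, and the list passed in all 10 fits. AngII plus OA replicate 5 had a low list mean, 3.13 against 3.74 to 4.10 in the rest of its group. Leaving out both of these libraries together was not tested. The list minus the fibroblast markers still differed by -0.542 (exact permutation p = 0.0317). A smaller share of these markers alone is therefore argued against. In AngII against vehicle, though, the markers had a mean log2 change of only 0.315, against 1.18 for the matrix list. They may not count the fibroblasts that make the matrix, so this test cannot decide on fewer of those cells. The list's call was lost with an estimated correlation (adjusted p = 0.358), and exact permutation of list means gave p = 0.0159, or 0.286 adjusted. That adjusted value is also what 1 list alone at the smallest p possible would have. With 0 genes called, an effect of oleic acid, or of its daily dosing, is a hypothesis that may be followed up.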

How the results depend on the processing

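The atrial covariate, the fits without AngII replicate 2 for AngII plus OA against vehicle, voom, the rescaling without mitochondrially encoded genes, the exact permutation of list means and the scalings of the cardiomyocyte test were chosen after the data were seen. For AngII against vehicle the 197 genes became 57 with a log2 change of at least 1, 72 without a filter, 109 after quantile normalization, 70 with only the 2 groups compared and 104 after rescaling; leaving out 1 library gave 49 to 425. The fold limit, the larger number of tests without a filter and the 10 libraries of the fit with only the 2 groups act by construction, but how much of each fall they account for was not tested; for the others, the left-out libraries included, the cause was not tested. Apart from the replicate block, the remaining alternatives gave 138 to 281 genes. AngII plus OA against AngII stayed at 0 (866 at an unadjusted p under 0.05 in limma, 0 by voom) except that leaving out 1 library gave 0 to 1, and AngII plus OA against vehicle stayed at 0 (441; 0 by voom) in all alternatives. The 20, 14 and 11 lists became 0, 0 and 0 with an estimated correlation and 12, 11 and 10 with a mean FPKM of at least 5. There the cell cycle, NADPH oxidase and Schwann cell lists had 1, 1 and 0 members left and no test, which ended 3 calls in AngII against vehicle, 2 in AngII plus OA against AngII and 1 in AngII plus OA against vehicle; the other lost calls were tested and missed (adjusted p from 0.0662 to 0.163). By exact permutation 0, 0 and 0 passed after adjustment. The design limits this test, since at least 6 lists at the smallest p possible, or more at a larger one, are needed. Lists at that p numbered 5, 0 and 1. Before adjustment 11, 5 and 5 lists had an exact permutation p under 0.05, fewer than the 20, 14 and 11 that camera called. The smallest p possible therefore does not account for all of the loss. Leaving out 1 library gave 18 to 22, 11 to 17 and 11 to 15. Of the called lists, 14 of 20, 10 of 14 and 7 of 11 passed in all such fits. The ribosomal protein list in AngII plus OA against AngII reversed without AngII replicate 2, to a median of 0.0148 and an adjusted p of 0.00290, from -0.08 and 0.945, with medians of -0.182 to 0.0148 leaving out 1 library; the cause was not tested. The slope became -0.450 with undivided libraries, where the shared libraries act by construction, and -0.316 to -0.0855 leaving out 1 library. With the replicate number as a block, 38 genes passed in AngII against vehicle, 0 in the others, and 20, 13 and 12 lists. Correlations of same-numbered libraries ran from -0.350 to 0.435 and exceeded 0.1 in 6 of 15 pairs, among them all 3 pairs of replicate 3; those of differently numbered libraries ran from -0.432 to 0.457 and exceeded 0.1 in 21 of 60. Libraries correlated best with their own number in 7 of 30 cases, so the numbers were not taken to pair the mice. Depth limits genes near 0.5 FPKM, which rest on a median of 57.1 reads per library.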

Other observations

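The test of Nppa against the atrial score was chosen after the result was seen, and its bound against the explanation was replaced once its value was known. The tests by other splits were set in advance.

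Several other lists moved. Against vehicle, AngII hearts had higher interferon-stimulated genes (22 of 22 members higher, median log2 change 0.30, adjusted p = 0.00606; adjusted p = 0.587 with an estimated correlation). Bst2 was at 72.0 ± 20.4 against 53.7 ± 8.92 FPKM and Iigp1 at 30.0 ± 17.6 against 21.6 ± 6.09. Glucocorticoid response genes were higher (median 0.95, adjusted p = 0.0257; adjusted p = 0.512 with an estimated correlation), and 3 of 8 rose adjusted over the list alone. Ddit4 was at 91.2 ± 41.0 against 36.3 ± 19.1 FPKM and Tsc22d3 at 75.4 ± 35.4 against 37.2 ± 7.98. Ribosomal protein genes were higher (28 of 28, median 0.25, adjusted p = 0.00875; adjusted p = 0.730 with an estimated correlation), with Rplp1 at 1125 ± 214 against 957 ± 289 FPKM and Rps24 at 807 ± 144 against 716 ± 80.4. Cholesterol synthesis genes were lower (median -0.15, adjusted p = 0.00218; adjusted p = 0.505 with an estimated correlation), with Hmgcs1 at 9.70 ± 2.86 against 10.6 ± 1.21 FPKM and Fdft1 at 9.05 ± 1.93 against 9.97 ± 0.847. Schwann cell markers were lower (median -0.32, adjusted p = 0.00429; adjusted p = 0.317 with an estimated correlation), and 1 of 3 fell adjusted over the list alone. Cdh19 was at 2.37 ± 0.299 against 2.65 ± 0.530 FPKM. In these 5 lists 0 members were called over all genes. Exact permutation of list means gave unadjusted p = 0.0873, 0.0794, 0.246, 0.357 and 0.0317 in that order. The interferon call was lost without AngII replicate 1 (0.0561) or vehicle replicate 3 (0.0693), the glucocorticoid call without AngII replicate 2 (0.278) or vehicle replicate 2 (0.233), and the ribosomal call without AngII replicate 2 (0.621), vehicle replicate 3 (0.0568) or vehicle replicate 4 (0.418). The ribosomal median was 0.15 without AngII replicate 2 and 0.12 without vehicle replicate 4. It was 0.11 after quantile normalization, 0.16 after shifting each library to 1 median and 0.10 with FPKM rescaled without mitochondrially encoded genes. The rescaled median of the interferon list was 0.18, and that of the cholesterol list -0.25, or -0.23 after the median shift. Over genes with a mean FPKM of at least 5 the interferon (0.163), glucocorticoid (0.0822), ribosomal (0.0662) and cholesterol (0.155) calls were lost, and the Schwann cell list had 0 members left and no test. Without AngII replicate 2 the cholesterol median was -0.05. Glycolysis genes did not pass (adjusted p = 0.783), and their median turned negative under the other scalings. The phosphofructokinase Pfkp rose by 0.79 (adjusted p = 0.0163), 2 of 20 adjusted over the list alone, and lost its call without AngII replicate 5 (0.0553). Renin-angiotensin and natriuretic signalling genes did not pass (adjusted p = 0.319), with 2 rising and 1 falling of 12 adjusted over the list alone. Among them Mas1, the receptor of angiotensin 1-7, fell by 0.64 (adjusted p = 0.0348), a call lost without AngII replicate 1 (0.0846), AngII replicate 2 (0.0520), AngII replicate 4 (0.0908), AngII replicate 5 (0.0602), vehicle replicate 2 (0.0706), vehicle replicate 3 (0.0600) or vehicle replicate 5 (0.0987). The circadian clock list did not pass (adjusted p = 0.538).

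Between AngII plus OA and AngII, glucocorticoid response genes were lower (8 of 8, median -0.61, adjusted p = 0.0108; adjusted p = 0.536 with an estimated correlation), a call lost without AngII plus OA replicate 2 (0.0695) or AngII replicate 2 (0.280). Interferon-stimulated genes were lower (median -0.25, adjusted p = 0.00235; adjusted p = 0.599 with an estimated correlation), a call lost without AngII replicate 1 (0.0753); the median was -0.15 without AngII plus OA replicate 5 and -0.39 without AngII replicate 3. Schwann cell markers were higher (median 0.24, adjusted p = 0.000870; adjusted p = 0.358 with an estimated correlation), and 1 rose adjusted over the list alone, with 0 members left for a test over genes with a mean FPKM of at least 5. Circadian clock genes (adjusted p = 0.126) passed without AngII plus OA replicate 3 (0.0439), AngII plus OA replicate 4 (0.0142) or AngII replicate 2 (0.00296), glycolysis genes (0.134) without AngII replicate 1 (0.0242) or AngII replicate 3 (0.0368) and cholesterol synthesis genes (0.303) without AngII replicate 4 (0.0147). Ribosomal protein genes (0.945) and renin-angiotensin genes (0.267) did not pass in all libraries. Between AngII plus OA and vehicle, circadian clock genes were higher (11 of 15, median 0.51, adjusted p = 0.00700; adjusted p = 0.357 with an estimated correlation), a call lost without vehicle replicate 2 (0.0699). The clock genes Nr1d2 and Tef were at 33.9 ± 7.96 against 22.1 ± 7.07 and 19.1 ± 8.08 against 11.7 ± 4.36 FPKM. Ribosomal protein genes were higher (median 0.16, adjusted p = 0.000124; adjusted p = 0.891 with an estimated correlation), a call lost without vehicle replicate 4 (0.394) and after quantile normalization (0.0698), with a median of 0.26 without vehicle replicate 2 and 0.03 without vehicle replicate 4. The ribosomal median was 0.07 after quantile normalization and 0.04 with FPKM rescaled. Cholesterol synthesis genes were lower (median -0.09, adjusted p = 0.000690; adjusted p = 0.569 with an estimated correlation), with -0.06 without AngII plus OA replicate 2 and -0.20 with FPKM rescaled. Glycolysis genes (0.108) passed without AngII plus OA replicate 4 (0.0382) or vehicle replicate 1 (0.0365). Interferon-stimulated (0.707), glucocorticoid (0.707), Schwann cell (0.740) and renin-angiotensin genes (0.803) did not pass.

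The lists of fatty acid synthesis, endoplasmic reticulum stress, neutrophil, B cell, adipocyte, erythroid, mesothelial, smooth muscle and skeletal muscle genes passed in none of the 3 comparisons with all libraries (adjusted p from 0.0763 to 0.914). Adipocyte markers passed against vehicle in AngII without AngII replicate 1 (0.0203), AngII replicate 3 (0.0457) or AngII replicate 5 (0.0141), and endoplasmic reticulum stress genes without AngII replicate 2 (0.0110). In AngII plus OA against AngII, adipocyte markers passed without AngII replicate 1 (0.0310) or AngII replicate 5 (0.0172), erythroid markers without AngII plus OA replicate 1 (0.00648), AngII plus OA replicate 3 (0.0190) or AngII replicate 2 (0.0149), neutrophil markers without AngII plus OA replicate 5 (0.00390) and fatty acid synthesis genes without AngII replicate 5 (0.0213). In AngII plus OA against vehicle, endoplasmic reticulum stress genes passed without AngII plus OA replicate 1 (0.00289), vehicle replicate 1 (0.0365) or vehicle replicate 3 (0.0163). Of the skeletal muscle genes, 1 rose in AngII against vehicle and 1 fell in AngII plus OA against AngII adjusted over the list alone. Camera compares a list with other genes, so its direction can differ from the sign of a list's median or mean. That was so, in lists that did not pass, for fatty acid uptake and renin-angiotensin genes in every comparison and for glycolysis, smooth muscle and atrial genes in AngII against vehicle. It was so for fetal, endoplasmic reticulum stress, immediate early and atrial genes in AngII plus OA against AngII, and for fatty acid synthesis, citric acid cycle and mesothelial genes in AngII plus OA against vehicle. The sign of the median changed with the scaling for smooth muscle and B cell markers in AngII against vehicle. It also changed for fatty acid uptake, endoplasmic reticulum stress and smooth muscle genes in AngII plus OA against AngII. In AngII plus OA against vehicle it changed for fatty acid uptake, fatty acid synthesis, glycolysis, interferon-stimulated and renin-angiotensin genes.

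Other splits of the same libraries were drawn, 100 of the 126 possible per comparison. For AngII against vehicle 3 of 100 splits, the real one included, gave as many as 197 genes, and the highest other gave 1235. As many as 20 lists came from 3 of 100, and the highest other gave 21. Both shares lay under 0.05, the bound set in advance against chance. That makes chance less likely and does not exclude it. The 20 lists rest on camera's preset correlation, and with an estimated correlation 0 passed. The split with 1235 genes set AngII replicates 1 and 3 with vehicle replicates 1, 3 and 4 against the rest. So many more genes than the real split gave points to a structure of the samples other than the groups, and what it reflects was not tested. These libraries lay between 2.0 and 28.4 on principal component 2, and the rest between -25.0 and -10.1 except AngII replicate 2 at 16.4. The weights of component 2 correlated across genes, which are not independent replicates, at -0.306 with GC content and 0.135 with log2 length. For AngII plus OA against AngII, the real split gave 0 genes by limma (866 at an unadjusted p under 0.05, 0 by voom; highest other 6). All 100 of 100 splits must reach 0, so that count tests nothing, and the same holds for AngII plus OA against vehicle (0 genes by limma, 441 at an unadjusted p under 0.05, 0 by voom; highest other 1). For lists, 30 of 100 splits of AngII plus OA against AngII gave 14 lists or more (highest other 22), and 33 of 100 of AngII plus OA against vehicle gave 11 or more (highest other 18). A slope as negative as -0.261 came from 8 of 100 splits, of which 89 gave a slope, and the most negative other was -0.394. The shares of these last 3 results did not lie under the bound of 0.05, so chance stays open for them.

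Nppa was tested against the atrial score across the 15 libraries, with the hypothesis that atrial tissue in the samples sets its level. Spearman's rho was 0.475 (permutation p = 0.0758, adjusted 0.0758) and Pearson's r 0.545 (permutation p = 0.0347, adjusted 0.0693 over the 2 measures). Without AngII replicate 2 and AngII plus OA replicate 2, the farthest from the median score, r was 0.355 (permutation p = 0.235) and rho 0.341, so the unadjusted pass of Pearson's r rests on those libraries, although such a p over 13 libraries does not show that the relation is absent. For deviations from the group means r was 0.638. The second highest Nppa, 97.3 FPKM, was in AngII replicate 5, which had an atrial score of 0.683. The hypothesis stays open.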
